A study of Bos taurus with 24 samples.

How the data were processed

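Total RNA of 16 bovine follicles from 16 heifers was hybridised to 24 two-colour arrays, 2 follicles per array. Per the labels' protocols, RNA was extracted with a column kit, labelled with dendrimer reagents, scanned on an Axon scanner and measured in GenePix Pro 4.0.1.12. The values the authors deposited are log ratios of both channels, taken here as log2. The largest absolute value was 6.32, above the 4.82 that a log10 ratio of 16-bit intensities can reach, so base 10 is excluded and natural logs are not. The background correction, spot filter and within-array normalization are not given in the sources used here. The direction is not stated either. Channel 1 is Cy5 per the labels and titles name the Cy5 follicle first, so Cy5 over Cy3 was taken as likely; the F test, its counts and all correlations are the same if every sign turns. Deposited array medians lay between -0.014 and 0.0064, so the arrays had been centred, and SDs ranged from 0.28 to 0.54, so they had not been brought to one scale. No scanner intensities were used here, and signal over background is unknown. Unused columns of per-sample values numbered 0.

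Features were named from the platform's annotation of 2007. Of 17418 features, 13605 had 1 gene symbol, 829 several and 2984 none, and features with several symbols were left unnamed. Of those with 1 symbol, 13575 were matched by gene ID to the RefSeq gene table of assembly ARS-UCD2.0, and 0 symbols changed. No coordinates are given, since the build behind the array is not given in the sources used here.

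Each array was centred on its median. Features with values on at least 20 arrays and estimable follicle effects were fitted with a follicle effect (1 for Cy5 and -1 for Cy3) and a common dye term, which leaves 8 residual degrees of freedom. Variances were moderated with limma 3.58.1 in R 4.3.3, and all follicle effects were tested together by an F test, with Benjamini-Hochberg adjustment at 0.05. Follicle effects explained 81.3% of the feature variance, where 65.2% would be expected by chance. Reversing the sign of any 1 array raised the residual sum of squares 1.02 to 1.41 times, so the dyes as labelled fitted best for each of the 24 arrays. For genes, all features of 1 symbol were averaged first. The SE of a level comes from array error over 3 arrays and holds no spread between animals, since each animal gave 1 follicle.

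There were 17 gene lists with 490 different genes, 337 of them measured, fixed before the data were examined along with the design, the alternatives and the rule for named genes. A list was tested against all genes by Fisher's exact test, two-sided, if at least 3 members were measured. The mean level of list members was correlated between lists of at least 5 members, by Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples. The association with CYP19A1 and the contrast of identifiers with and without C were fitted by limma on the 16 follicle levels, with camera at a preset correlation of 0.01 for lists. The rule named the 12 genes of largest SD past the threshold, the 2 members of smallest p in each list, 8 genes of steroid and gonadotrophin biology where measured, and genes past the threshold in the other comparisons. IGHG1 and genes in the closing section outside that rule were named after their values were seen.

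Alternatives changed the centring, the scaling between arrays, the minimum number of arrays, the dye term, the moderation, the choice of feature per gene, the list score, and the arrays or follicles included. An association with INHBA, 3 more lists, fits without follicle J980, and the endothelial list without PECAM1 were added after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

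The F test, the contrast with C and the association test were tried on simulated data with the real loop and array error. The permutation tests of correlations were not, and they take follicle levels as exchangeable although their errors are correlated through the loop. In the comparison between follicles of 9026 genes, the F test recovered 52.5% of 200 genes given a level SD of 0.25, with 5 false calls. At an SD of 0.5 it recovered 93.5% with 14 false calls, and at an SD of 1 it recovered 99.5% with 13. With no differences it made 0 calls. In the contrast of follicles with and without C, 75.5% of 200 genes shifted by 0.5 were recovered among 9026. The association test was less sound. With CYP19A1 given a level SD of 0.1 and 200 genes made to follow it, 3 were recovered and 26 calls were false. With CYP19A1 set constant, 6 of 20 simulations of 9025 genes made false calls, up to 1970, and 13.9% of unadjusted p were under 0.05 on average. With errors drawn independently for each follicle level instead of through the loop, 2 of 20 did, with at most 1 call. With the estimated INHBA levels, which vary far beyond array error, 2 of 20 did, with at most 1 call, but 7.32% of unadjusted p were under 0.05 on average and up to 15% in a single simulation, so that test was too lenient. With C, 0 of 20 did, and 3.24% of unadjusted p were under 0.05, so that test was conservative.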

Results

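RNA was measured from the largest ovarian follicle of each of 16 heifers, with follicle diameters of 8 to 12 mm. Each of 24 two-colour arrays compared 2 follicles, and each follicle was on 3 arrays, in a connected loop of 24 different pairs. All 16 follicles were labelled with both dyes, 8 of them with Cy5 on 2 arrays and 8 with Cy5 on 1. The labels give an identifier for each follicle and no treatment, stage or dominance status, so the comparisons are between follicles. The series title names follicle selection, the process in which 1 follicle of a growing cohort becomes dominant. The table held 17418 array features, with 16094 to 17028 values per array, and 12553 features had a value on all arrays. The number of arrays limits the precision, and the median SE of a follicle level was 0.13.

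Of the 12 genes with the largest SD between follicles, 4 were interferon-induced. ISG15, a ubiquitin-like protein, had an estimated log2 level of 3.11 ± 0.12 (SE, 3 arrays) in follicle J980 and -1.41 ± 0.12 in follicle 46. MX1, an antiviral GTPase, was likewise highest in J980 at 3.03 ± 0.11 and lowest in follicle 26 at -1.53 ± 0.10. IFI6 and IFI27 were both highest in follicle 861, at 2.43 ± 0.14 and 2.31 ± 0.26. IFI6 was lowest in follicle 46 at -1.37 ± 0.14 and IFI27 in C12 at -1.94 ± 0.28. Levels are relative to the mean of the 16 follicles. The log base is taken as log2 and the direction as Cy5 over Cy3. That direction is likely from the order of dyes and channels in the labels but is not stated, and with the inverse ratio every sign would turn.

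**Figure D1:**
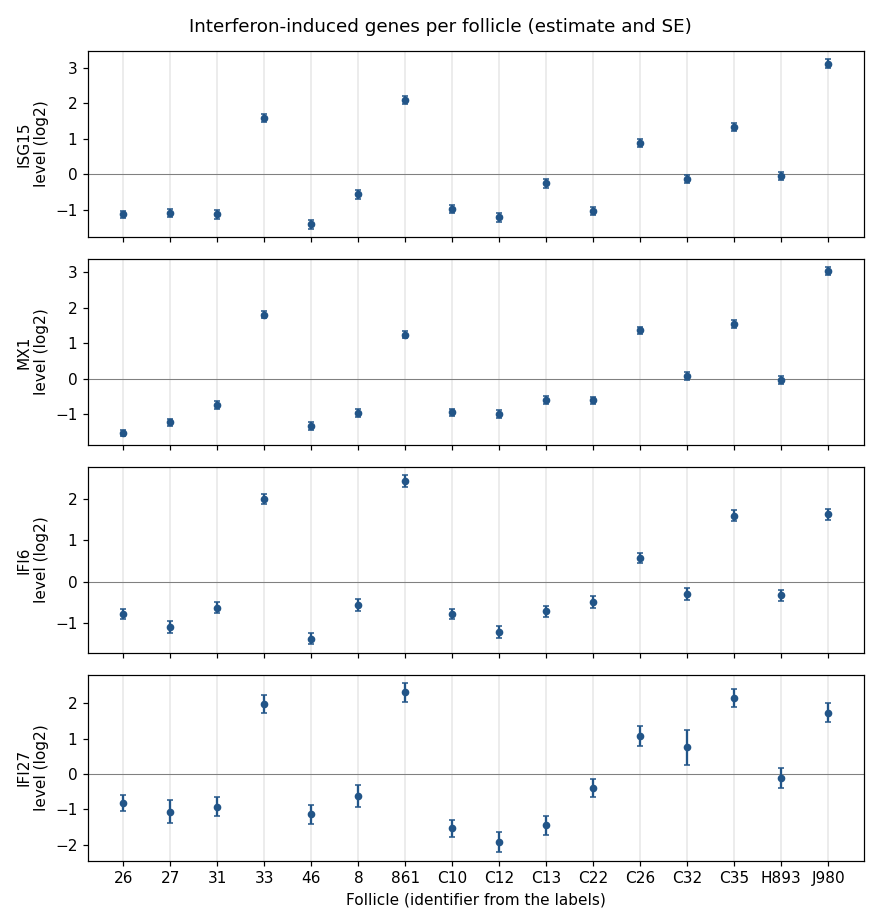
Estimated log2 level of ISG15, MX1, IFI6 and IFI27 in each of the 16 follicles relative to their mean, taking the ratio as Cy5 over Cy3; points are estimates from 3 arrays, bars are SE, and each panel has its own scale. MX1 lay above 1 in 5 follicles and below -0.5 in 9.

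Of 9026 genes tested, 1061 (11.8%) differed between follicles by the limma-moderated F test with Benjamini-Hochberg adjustment. Of 16358 features, 1994 (12.2%) did, and 450 of these had no single gene symbol. At an unadjusted p under 0.05 there were 4417 features. The median SD of follicle levels was 0.29 for the genes past the threshold and 0.17 for all genes. The error in this test is array error, so it compares these 16 RNA samples. Of the genes past the threshold, 421 were lowest in J980 and 91 highest there. Without J980 and its 3 arrays, 673 genes passed, of which 576 also passed with all 16 follicles. The count was 608 without a term for dye bias and 589 without moderation of the variances. Leaving out a single array gave 681 genes without the array of follicle 33 (replicate 2) and 688 without that of follicle 31 (replicate 2).

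Beyond the interferon-induced genes, 8 others were among the 12 with the largest SD. TNFAIP6, a hyaluronan-binding protein of the expanding cumulus matrix, was highest in 861 (1.84 ± 0.37) and lowest in J980 (-2.40 ± 0.37). C19H17orf80 was highest in C32 at 2.18 ± 0.15, and TMEM176B, a membrane protein, was highest there at 1.25 ± 0.15. Both were lowest in follicle 46, at -1.21 ± 0.16 and -2.12 ± 0.16. PECAM1, ORMDL2, CTSH, SLC35D2 and PLPBP were all highest in C26, at 2.38 ± 0.31, 2.17 ± 0.29, 1.97 ± 0.25, 1.87 ± 0.37 and 1.94 ± 0.16. Each of these 5 genes had 1 feature, and each followed the level of the immunoglobulin heavy chain gene IGHG1 across the 16 follicles. The Pearson r with IGHG1 was 0.983 for PECAM1, 0.989 for ORMDL2, 0.992 for CTSH, 0.962 for SLC35D2 and 0.995 for PLPBP. Spearman's rho ranged from 0.941 to 0.988. The permutation p of r and of rho was 1e-05 in each case, the smallest that 100000 permutations give, with adjusted values of 1.2e-05 and 1.7e-05 over 15 relations examined. Without C26 and C32, r ranged from 0.927 to 0.991. These genes were picked out for that relation after the values were seen, so the p-values are no independent support for it.

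In the granulosa cell list INHBA and FST had the largest SD between follicles. INHBA, the beta A subunit of activin and inhibin, was at -2.69 ± 0.17 in J980 and at 1.04 ± 0.17 in follicle 861 (adjusted p = 6.11e-05). FST, which encodes the activin-binding protein follistatin, was also lowest in J980 at -2.05 ± 0.10 and highest in 861 at 1.11 ± 0.10. INHA, the alpha subunit of inhibin, was highest in C32 at 0.71 ± 0.14 and lowest in J980 at -0.77 ± 0.14, and its call was lost without the dye term. In all, 8 of 15 measured members of this list differed, 11 when adjusted over the list alone, which exceeded the share of all genes (Fisher's exact test, adjusted p = 3.42e-04). CYP19A1, the aromatase that makes oestradiol, did not pass. Its levels had an SD of 0.08 against an array error of 0.19 (adjusted p = 0.844). FSHR, the FSH receptor, ranged from -0.48 ± 0.20 to 0.26 ± 0.19 without passing (adjusted p = 0.255). LHCGR, STAR and CYP17A1 were not among the named features.

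**Figure D2:**
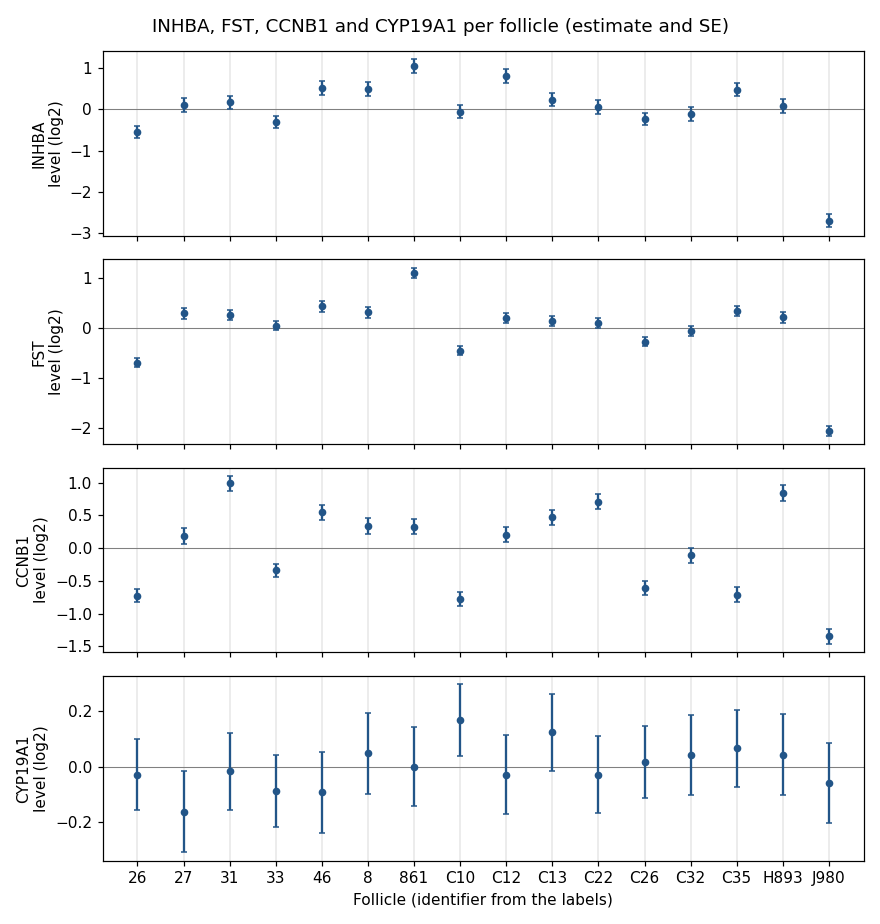
Estimated log2 level of INHBA, FST, CCNB1 and CYP19A1 in each of the 16 follicles relative to their mean, taking the ratio as Cy5 over Cy3; points are estimates from 3 arrays, bars are SE, and each panel has its own scale. INHBA is at -2.69 in J980, while CYP19A1 stays between -0.16 and 0.17.

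Genes of steroid synthesis, ovulation and the corpus luteum also differed. FDX1, the electron donor of side-chain cleavage, was highest in H893 at 0.72 ± 0.10 and lowest in follicle 46 at -0.90 ± 0.10. HSD3B1, which converts pregnenolone to progesterone, ranged from 0.39 ± 0.11 in C12 to -0.63 ± 0.11 in J980. CYP11A1, the side-chain cleavage enzyme, ranged from 0.95 ± 0.25 in C12 to -1.06 ± 0.25 in J980 (adjusted p = 0.038), and this call was lost in 19 of 24 fits that each left out 1 array. The theca list had 6 of 10 members past the threshold, 7 when adjusted over the list alone (adjusted p = 7.62e-04). The luteal list had 5 of 7, 6 over the list alone (adjusted p = 7.62e-04), and SCARB1, the HDL receptor in both lists, ranged from 0.36 ± 0.12 to -0.56 ± 0.13. The 4 features of SCARB1 disagreed in part, with a median pairwise r of 0.517 and a lowest of -0.177. In the luteal list the mean level was lowest in J980, at -0.42. The luteal call was lost without the dye term, without moderation and without 1 array of follicle 33 (replicate 2; adjusted p = 0.124), and that of SCARB1 without the dye term. In the ovulation list, TNFAIP6 and the transcriptional regulator CITED2 were among 4 of 8 members that differed, 5 over the list alone (adjusted p = 0.012). CITED2 was highest in J980 at 0.76 ± 0.16. The call of this list was lost with features on all 24 arrays and without moderation.

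Cell cycle genes had the smallest p of the lists. Of 27 members measured, 16 differed, 20 over the list alone (adjusted p = 7.05e-08). CCNB1, the mitotic cyclin, was highest in follicle 31 at 0.99 ± 0.11 and lowest in J980 at -1.35 ± 0.12. H2AZ1, a histone variant, had the same extremes, 0.83 ± 0.13 and -1.13 ± 0.14. The mean of the list was -0.58 in J980, and the next lowest follicle was C10 at -0.19. The apoptosis list had 8 of 18 members past the threshold, 10 over the list alone (adjusted p = 9.33e-04). BIRC5, an inhibitor of apoptosis that is also a mitotic protein, ranged from 0.79 ± 0.12 in follicle 31 to -1.47 ± 0.13 in J980. BCL2L1, a BCL2 family member, was highest in C26 at 1.29 ± 0.09, and its call was lost when features on fewer than 20 arrays were admitted.

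Growth factor genes differed with uneven shares. In the IGF list 5 of 12 members differed, 6 over the list alone (adjusted p = 0.012). IGFBP2, a binding protein for IGF, ranged from 0.82 ± 0.15 in 861 to -1.26 ± 0.15 in J980, and IGFBP6 from 0.94 ± 0.10 in C10 to -0.60 ± 0.11 in J980. The IGF call was lost with features on all 24 arrays and without the dye term. In the list of the TGF-beta and BMP family, 3 of 15 members (20%) passed, 6 over the list alone. With so few members this share could not be told from the 11.8% of all genes (Fisher's exact test, adjusted p = 0.466). Without 1 array of J980 (replicate 2) this list passed (adjusted p = 0.0142). Among its members BMP7, a bone morphogenetic protein, ranged from 0.59 ± 0.11 in 861 to -1.47 ± 0.11 in J980. SMAD2, a signal transducer of activin, ranged only from 0.29 ± 0.08 to -0.37 ± 0.08, and its call was lost with 1 feature per gene, without the dye term and without J980. The 3 features of SMAD2 had a median pairwise r of 0.458 and a lowest of -0.127.

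Metabolic and protein-folding lists also held more differing genes than expected from all genes. The cholesterol list had 9 of 18 (adjusted p = 2.99e-04), and the same 9 of 18 in count when adjusted over the list alone. SQLE and IDI1, both enzymes of cholesterol synthesis, were highest in H893, at 1.19 ± 0.11 and 0.76 ± 0.12. SQLE was lowest in C32 at -1.13 ± 0.11 and IDI1 in follicle 46 at -0.75 ± 0.12. Of 53 oxidative phosphorylation genes, 20 differed, 30 over the list alone (adjusted p = 5.05e-06). The 20 include ATP5F1A, and a feature averaged into that gene followed IGHG1 (r = 0.985). NDUFC1, a subunit of the first respiratory complex, ranged from 0.51 ± 0.09 in 861 to -0.63 ± 0.09 in J980. The call of UQCRH, a subunit of the cytochrome bc complex, was lost with 1 feature per gene, where its 2 features had r = 0.046. The chaperone list had 8 of 23 members past the threshold, 13 over the list alone (adjusted p = 0.0055). HSPA5, an endoplasmic reticulum chaperone, was highest in follicle 46 at 0.60 ± 0.15 and lowest in J980 at -1.01 ± 0.15. HSP90B1, another one, was lowest in C13 at -1.11 ± 0.13. Of 60 ribosomal proteins 10 differed, 14 over the list alone (adjusted p = 0.28). RPL31 and RPL37A lost their calls with 1 feature per gene. With features on all 24 arrays the ribosomal list passed (adjusted p = 0.00716), as it did without 1 array of J980 (replicate 1; adjusted p = 4.38e-04).

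Connective tissue and blood-cell genes varied between follicles as well. In the extracellular matrix list 14 of 28 members differed, 17 over the list alone (adjusted p = 5.05e-06). POSTN, encoding periostin, was highest in C26 at 1.09 ± 0.13 and lowest in H893 at -1.06 ± 0.15, and its 3 features had a median pairwise r of 0.933. FBLN1, a fibulin, ranged from 0.73 ± 0.09 in C10 to -0.68 ± 0.10 in H893. The list of smooth muscle and stroma had 2 of 12 members past the threshold, 3 over the list alone (adjusted p = 0.686). These were S100A4, with a range of 0.72 ± 0.15 to -0.75 ± 0.17, and ACTA2. The S100A4 call was lost without moderation. The ACTA2 call was lost in 20 of 24 fits that left out 1 array, and its 4 features had a median pairwise r of -0.0104 and a lowest of -0.555. Among genes of leukocytes and erythrocytes, 10 of 25 differed, 12 over the list alone (adjusted p = 7.62e-04). CXCR4, a chemokine receptor, was highest in J980 at 2.07 ± 0.20 and lowest in follicle 27 at -0.82 ± 0.20. BOLA-DRA, an antigen-presenting MHC molecule, ranged from 1.24 ± 0.14 in C32 to -0.83 ± 0.14 in follicle 46. Of 11 endothelial markers, PECAM1 passed, 2 over the list alone (adjusted p = 1), and the PECAM1 call was lost without moderation. CLDN5, the next smallest, had an adjusted p of 0.0558. In the oocyte list 2 genes were measured and ZP3, a zona pellucida protein, passed with a range of 0.73 ± 0.15 to -0.51 ± 0.18. Its call was lost in 18 of 24 fits that left out 1 array, and ZP2 did not pass (adjusted p = 0.248).

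**Figure D3:**
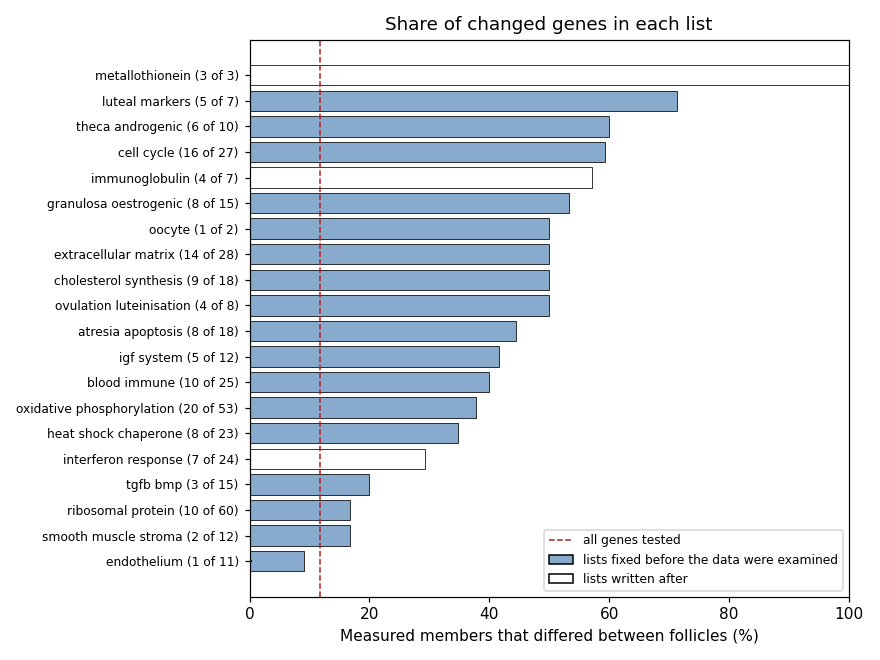
Share of each list's measured members that differed between follicles, in percent on an axis from 0 to 100, with the number of members beside each name; the dashed line marks all genes tested, at 11.8%. Filled bars are lists fixed before the data were examined and open bars 3 lists written afterwards; the cell cycle list reached 59.3%.

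Of 16 lists tested by Fisher's exact test, 12 passed. The test takes genes as independent. The lists hold well-studied genes, and no signal intensities were used here to match them to other genes of like abundance.

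Some lists rose and fell together across follicles, led by matrix genes with genes of smooth muscle and stroma. For that pair r was 0.905 and rho 0.900 over the 16 follicles, and r was 0.875 without C10 and C26. The permutation p of r and of rho was 1e-05, the smallest possible, with adjusted values of 6e-04. Permutation takes the 16 levels as exchangeable, although their errors are correlated through the loop. It was not simulated, so its p may be too small here and below. Cell cycle and oxidative phosphorylation had r = 0.812 (permutation p = 8e-05, adjusted 0.0032) and rho = 0.856 (permutation p = 1.1e-04, adjusted 0.0044), with r = 0.724 without follicles 31 and J980. Smooth muscle and ribosomal proteins had r = 0.818 (permutation p = 1.7e-04, adjusted 0.0051) and rho = 0.782 (permutation p = 5e-04, adjusted 0.012), with r = 0.739 without 861 and J980. IGF and ribosomal lists had r = 0.708 (permutation p = 0.00206, adjusted 0.0353) and rho = 0.724 (permutation p = 0.00231, adjusted 0.0396), with r = 0.787 without 861 and C32. The call of this pair was lost with list medians (adjusted p = 0.154), with members scaled to SD 1 (adjusted p = 0.098), without J980 and its arrays (adjusted p = 0.0652), and without the level of follicle 31, C10, C13, C26, C35 or J980 (adjusted p from 0.0545 to 0.104). That of smooth muscle with ribosomal proteins was lost without J980 and its arrays (r = 0.60, adjusted p = 0.146) and with members scaled to SD 1 (adjusted p = 0.0522).

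In all, 10 of 120 pairs passed by r, all 10 positive. By rho 7 passed, 5 of them among these 10. The other 2 were matrix with ribosomal proteins (rho = 0.724, permutation p = 0.00201, adjusted 0.0396; r = 0.664, permutation p = 0.00539, adjusted 0.0582) and, negatively, cell cycle with endothelium (rho = -0.797, permutation p = 4.7e-04, adjusted 0.012; r = -0.596, permutation p = 0.011, adjusted 0.0779). The endothelial and blood-cell lists had r = 0.891 and rho = 0.915 (both permutation p = 1e-05, adjusted 6e-04), and r = 0.912 without follicles 26 and C32. This relation rested on PECAM1: without it, r was 0.28 (adjusted p = 0.53), and with features on all 24 arrays it was -0.18. The pair of cell cycle with endothelium uses the same list and was not examined without PECAM1. The granulosa list with the cell cycle list had r = 0.756 (permutation p = 0.00238, adjusted 0.0357), which fell to 0.345 without follicles 26 and J980, so it rested on those follicles; its rho was 0.576 (permutation p = 0.0223, adjusted 0.191). The granulosa list also passed with oxidative phosphorylation (r = 0.714, permutation p = 0.00198, adjusted 0.0353) and with the TGF-beta and BMP list (r = 0.715, permutation p = 0.00403, adjusted 0.0484). The latter list passed with chaperones (r = 0.716, permutation p = 0.00355, adjusted 0.0473), and smooth muscle with the luteal list (r = 0.721, permutation p = 0.00121, adjusted 0.029). Their rho was 0.515, 0.335, 0.450 and 0.671 (permutation p = 0.0444, 0.203, 0.083 and 0.00536; adjusted 0.273, 0.451, 0.334 and 0.0715). Without the 2 follicles farthest in the first-named list, r was 0.580, 0.181, 0.226 and 0.539, so both relations of the TGF-beta and BMP list rested on those follicles. Without J980 and its arrays, 5 pairs passed. Leaving out only its level made some negative relations larger, picked here after their values were seen. Matrix with oxidative phosphorylation moved from r = -0.394 to -0.775, and smooth muscle with oxidative phosphorylation from -0.235 to -0.755. The granulosa list moved from r = -0.031 to -0.688 with smooth muscle and from -0.158 to -0.641 with matrix. Positive calls alone therefore do not describe the remaining follicles. Of the 10 pairs, those of matrix with smooth muscle and of cell cycle with oxidative phosphorylation passed in every setting run, and each of the others lost its call in at least 1.

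No gene was associated with CYP19A1 across follicles. Of 9025 genes, 0 passed by limma, 200 had an unadjusted p under 0.05 where 451 would be expected by chance, and 0 passed by Spearman's test. No list passed by camera either. CYP19A1 itself varied less than array error, so this does not test which genes vary with oestradiol synthesis.

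The 7 follicles with C in their identifier and the other 9 did not differ in any single gene, and what the letter stands for is not given. Of 9026 genes, 0 passed by limma and 233 had an unadjusted p under 0.05, where 451 would be expected by chance. With the letter fitted directly on the arrays and array error in place of the spread between follicles, 2 genes passed. These were EPB41L2, a membrane skeleton protein, at -0.62 ± 0.09 (SE; adjusted p = 0.00516), and PCDH1, a protocadherin, at -0.33 ± 0.06 (adjusted p = 0.0482), both lower with C and both named only after their values were seen. By camera with a preset correlation of 0.01, 4 lists were shifted upward in follicles with C. The median differences were 0.05 for ribosomal proteins (adjusted p = 0.0029), 0.12 for leukocyte and erythrocyte genes (adjusted p = 0.0029), 0.07 for matrix (adjusted p = 0.0158) and 0.07 for smooth muscle and stroma (adjusted p = 0.0193). None of these held with an estimated correlation, where the adjusted p was 0.559, 0.619, 0.622 and 0.559.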

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

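All tests of explanations in this part were chosen after the result was seen. Follicle J980 was far from the others in 2 of 3 results where a sample stood out among the follicles with or without C. Its INHBA level was -2.69, where the next of the 9 follicles without C was at -0.55. Its chaperone list was at -0.32, where the next of these 9 was at -0.06, but over all 16 follicles C13 was next, at -0.21. In the oocyte list, C32 was at 0.40 among the 7 follicles with C, and the next of these was at 0.06, while over all 16 follicle 27 was next, at 0.22. In all 68 groups of values were examined and 3 stood out, where about 5% would by chance.

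The distance of J980 was weighed against technical explanations. A single faulty array is argued against: with any of its 3 arrays left out, INHBA, FST and the cell cycle list of J980 stayed below the range of the other follicles, and 0 of 9 such levels fell within it. Noisier arrays are argued against for these 3 levels, which leaving out 1 array moved by at most 4.09% of their gap to the next follicle; INHBA stayed between -2.64 and -2.73. For the spread over all genes, noisier arrays stay open. The SD shared by the log ratios of J980 to its 3 partners was 0.234, above the highest of the other follicles, 0.149, but the lowest of its pairs of arrays shared 0.124. With levels from each array alone, the lowest pair shared 0.101, where the highest other follicle had 0.155. The residual SDs of its arrays, 0.274 to 0.296, were above the highest elsewhere, 0.258, but relative to the SD of each array, at 0.522 to 0.625, they lay within the 0.434 to 0.815 of the others. A lower share of granulosa cells is argued against only weakly as the sole source of the fall in INHBA (-2.69) and FST (-2.05). Such a share would lower other genes confined to granulosa cells about as far. Of the other granulosa genes, those past the threshold lay between -1.02 (GJA1) and -0.01 (AMH) in J980. Whether they are confined to these cells was not tested. CYP19A1 and FSHR did not pass, and signal over background is unknown, so their levels near 0 carry no weight here. As a partial source, a lower share stays open. Without INHBA and FST, which mark the pattern, the 13 other measured granulosa genes had a median level of -0.08 in J980, and their SD of 0.459 was 2.81 times their median SE, below the 3 times taken as too uneven for such a share. Of these, 6 lay more than 2 SE below 0, from -0.40 for NR5A2 to -1.02 for GJA1, and the rest from -0.08 to 0.44, with CYP19A1 at -0.06, AMH at -0.01 and FSHR at 0.09. RNA quality was not measured here, and no other biological explanation was tested because the labels give no stage or treatment.

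The interferon-induced genes that differed between follicles had correlated levels. Of 24 measured members of the interferon list, 7 were past the threshold, and only these were correlated. Among them the median r over 21 pairs was 0.757, and without J980 it was 0.736, so that follicle alone does not set the pattern. A larger share of leukocytes could contribute, and with 16 follicles the interval of its correlation is too wide to exclude it. The mean of these genes had r = 0.377 with 24 leukocyte and erythrocyte genes (95% interval -0.146 to 0.735; permutation p = 0.15, adjusted 0.15), rho = 0.379 (permutation p = 0.15, adjusted 0.16) and r = 0.368 without J980 and follicle 33. No other biological explanation was tested, and the labels record no infection or vaccination.

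Features of other genes followed the immunoglobulin features. At r above 0.95 with IGHG1 there were 116 features past the threshold, of which 46 were named for immunoglobulins, 51 had no single name and 19 were named for 19 other genes. For the 9 genes with other features, the level of the gene itself is argued against only weakly as the common source. These 15 features had a median r of 0.0848 with IGHG1 (SD 0.365), far below 0.7. Whether they vary beyond array error was not examined, and dim features could have a low r in any case. The level of the gene itself stays open for ATP5F1A, with another feature at r = 0.728, and EPHX1, with others at 0.567 and 0.188. For the other 10, among them PECAM1, there were 0 other features, so the level of the gene itself and another source cannot be told apart. Endothelial cells are argued against for PECAM1 only weakly. Its median r with 10 other endothelial markers was -0.153, but PECAM1 alone of that list passed the F test. Signal over background is unknown, so dim markers cannot be told from unchanged ones. Position on the array stays open. All 19 features lie at 7 of the 24 second numbers in the spot identifiers, which hold 25.7% of the named features compared. Of these, 3.81% exceeded r = 0.7 against 0.764% elsewhere. All 46 features named for immunoglobulins lie there too, so a smear and the order in which clones were printed cannot be told apart. Carry-over or misassigned clones at single spots were not tested and may remain.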

How the results depend on the processing

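Fits without J980, the association with INHBA and the endothelial list without PECAM1 were chosen after the results were seen, as were the reassignments of arrays. Without the dye term, 1245 features and 608 genes differed between follicles, and without moderation 1190 and 589; without J980 and its arrays, 673 genes did. Pairs of lists that passed numbered 5 with arrays scaled, 17 with features on all 24 arrays, 5 with list medians, 3 with members scaled to SD 1 and 5 without J980 and its arrays. With features on all 24 arrays the endothelial and blood-cell lists reversed to r = -0.18. The contrast with C gave 2 genes when fitted on array error, and its lists numbered 0 with an estimated correlation, as did those associated with INHBA. Genes associated with INHBA numbered 38 with arrays scaled and 1 without the arrays of J980. Fewer arrays and follicles enter the fits without J980; otherwise the cause was not tested.

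Leaving out each array in turn gave 1382 (without follicle 33, replicate 2) to 2348 features (without J980, replicate 1), 681 to 1172 genes and 11 to 13 lists. Leaving out each follicle gave 5 to 13 pairs of lists, 0 to 0 genes for CYP19A1 and for C, and 4 to 628 for INHBA. Pairs numbered 5 without C10, 5 without C26 and 6 without J980. INHBA genes numbered 274 without 861 and 4 without J980. Counts of lists stayed within 10 to 13 in every setting run, and the counts for CYP19A1 stayed at 0. The permutation of arrays argued against chance. Of 100 assignments of arrays to the loop, 1, the real one, gave as many genes (1061, highest other 1) and 1 as many features (1994, highest other 2). The arrays differed in scale, with SDs of 0.28 to 0.54, so they were not fully exchangeable. For C and for CYP19A1 the real count was 0, which all 100 of 100 splits or reassignments must reach (highest other 3 for each), so they decide nothing. No paired analysis was possible because the labels pair no follicles; replicate numbers here only name arrays in accession order. Signal over background is unknown, so what dim spots limit could not be assessed.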

Other observations

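All lists, relations and tests in this part were chosen after the data had been seen, and INHBA was taken up after CYP19A1 gave no associated gene. Metallothioneins, small metal-binding proteins, differed strongly between follicles. MT1A ranged from 1.83 ± 0.09 (SE, 3 arrays) in follicle 861 to -1.10 ± 0.08 in C10, and MT2A from 1.63 ± 0.09 to -1.09 ± 0.08 in the same follicles. MT3 was highest in follicle 46 at 1.28 ± 0.14 and lowest in C35 at -0.97 ± 0.14. All 3 measured members passed. MT1A and MT2A had r = 0.996 and rho = 0.997 (both permutation p = 1e-05, the smallest possible, adjusted 1.2e-05 and 1.7e-05), and r = 0.993 without 861 and 46. The probes of such similar genes can cross-hybridise, so these are not independent measurements.

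IGHG1, an immunoglobulin heavy chain, varied with leukocyte genes. It was highest in C26 at 1.71 ± 0.16 and lowest in follicle 31 at -1.11 ± 0.17, and 49 of its 55 features passed. JCHAIN, which joins antibody polymers, was also highest in C26, at 1.14 ± 0.16. In the immunoglobulin list 4 of 7 members passed, and in the interferon list 7 of 24. The B-cell genes CD79A, CD79B and MZB1 of the immunoglobulin list did not pass (adjusted p = 0.548, 0.96 and 0.477). IGHG1 and the mean of 24 leukocyte and erythrocyte genes had r = 0.917 (permutation p = 1e-05, adjusted 1.2e-05), rho = 0.844 (permutation p = 6e-05, adjusted 7.5e-05) and r = 0.828 without C26 and C32. Singly, 12 of the 24 had r above 0.7. CXCR4 instead followed the mean of the 7 interferon genes past the threshold. Its r was 0.953 and its rho 0.932 (both permutation p = 1e-05, adjusted 1.2e-05 and 1.7e-05), and r was 0.968 without J980 and 33.

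Across the 16 follicles 421 of 9025 genes were associated with INHBA by limma, 324 positively and 97 negatively. FST had a slope of 0.78 ± 0.07 (SE; adjusted p = 6.33e-06) and BMP7 of 0.57 ± 0.04 (adjusted p = 6.22e-07), and CLDN5, a tight junction protein of endothelium, had -0.64 ± 0.15 (adjusted p = 0.0201). By camera the cell cycle, oxidative phosphorylation, granulosa and chaperone lists rose with INHBA and the leukocyte list fell (adjusted p = 5.85e-08, 7.96e-04, 7.96e-04, 0.00165 and 0.019). With an estimated correlation none held (adjusted p = 0.155, 0.329, 0.0725, 0.329 and 0.567). Of 100 assignments of the INHBA levels to follicles, 2 gave as many genes, with 443 in the highest other. The 5 other assignments that left the level of J980 in place gave 443, 408, 113, 14 and 5 genes and the rest at most 3. The count thus follows the place of J980, which 6 of the 100 kept, and with 1 place among 16 follicles this does not decide on chance. Without the level of J980, 4 genes passed, BMP7, FST, MRPS6 and ST3GAL4, and with its arrays removed 1 did, BMP7, at a slope of 0.64 ± 0.08. Of the 421 slopes, 403 kept their sign without J980, but these genes were chosen in a fit that holds the same remaining follicles. The slopes without it had a median of 0.784 of those with it and the SEs a median of 2.01 times. Dropping the follicle with the extreme INHBA level widens the SEs by itself. These values therefore do not decide whether the associations persist. The slope of CLDN5 was -0.97 without J980 (adjusted p = 0.27) and that of BIRC5 0.57 against 0.55 with it. With arrays scaled, 38 genes passed. BMP7 was thus still called without J980, and its r with INHBA was 0.895 without J980 and 861. The association test was found too lenient, however, and it was not simulated without J980.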
